A study of Caenorhabditis elegans with 12 samples.

How the data were processed

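RNA was measured in whole adult Caenorhabditis elegans of 2 genotypes at 2 ages, with 3 biological repeats per group per the labels, which gave 12 libraries. Per the labels' protocols, the animals were fed OP50 bacteria, were moved to plates with 50 µM FUdR at the last larval stage or as young adults, were harvested in M9 buffer, washed and frozen in liquid nitrogen, and total RNA was extracted with RNAiso plus and made into unstranded libraries with a TruSeq RNA kit. The submitters' processing notes name STAR 2.7.0e, RSEM 1.3.1 and DESeq2 1.22.2 and the genome build WBcel235 (ce11), without saying what each was used for. The deposited values were whole-number counts per gene and library, not normalized, as their unequal totals showed. Whether they were rounded from estimates that split reads among similar genes, and how reads matching several genes were counted, is not given in the sources used here. The libraries did not mark strand, so reads of overlapping and antisense genes cannot be told apart. Values of members of families with near-identical copies, such as the msp and histone genes and vit-3, vit-4 and vit-5, are uncertain.

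Each of the 46778 genes listed was matched by its identifier to the WBcel235 annotation, which held 46603 of them and gave a gene symbol to 43818. No entry failed to name a gene. No read was counted for 24222 genes in any library. Coordinates are 1-based and come from that annotation.

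Total counts ran from 20322128 to 47447136 per library. A count of 0 allows up to 3 counts, for counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries of a group held identical values, and each pair differed by more than sampling noise (chi-square over degrees of freedom from 13.3 to 124.3), so all 12 were used as separate replicates. Across genes, Pearson's r of log2 CPM (counts scaled to a common library total) between replicates was 0.977 to 0.991. The biological coefficient of variation fitted within a group was 0.231 for wild type at day 1, 0.152 for wild type at day 9, 0.233 for daf-2 at day 1 and 0.222 for daf-2 at day 9.

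Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM scaling, the package's filter on low counts (minimum count 10) and 1 fit of the 4 group means over the 12 libraries, which left 15523 genes. The 5 comparisons were day 9 against day 1 in each genotype, daf-2 against wild type at each age, and the interaction, the log2 change with age in daf-2 minus that in wild type. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The standard error (SE) of a log2 change was its size divided by the square root of its F statistic. Levels are CPM, as mean ± SD over the 3 libraries of a group.

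A total of 37 gene lists, covering immunity, insulin signalling, stress responses, metabolism, the germ line and tissues, were fixed before the data were examined. The DAF-16 target and DAF-16-repressed lists hold genes that the literature gives as raised or lowered in daf-2 mutants. The directions of these 2 lists in the genotype comparisons were thus known beforehand. Members called were counted with adjustment over all genes and again adjusted over the list alone. Each list was also tested against the other genes with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the 37 lists of a comparison. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance 1 way, served as checks. Some genes belong to several lists: the DAF-16 target list shares 5 genes with the trehalose, glyoxylate and gluconeogenesis list, 4 with the antioxidant list and 3 with the cytosolic heat shock list, and the DAF-16-repressed list shares 3 with the PMK-1 effectors. Shares of a library taken by 8 gene classes were compared by exact two-sided permutation tests, 32 in all, which cannot go below p = 0.1 with 3 libraries against 3. The 2 ageing comparisons share no library, nor do the 2 genotype comparisons, so their overlaps were set beside n1 × n2 / N, the overlap of independent lists.

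The named genes were chosen by a rule set before the data were examined. It took the 5 largest and 5 smallest log2 changes among called genes with a mean of at least 10 CPM in the higher group, at least 10 counts summed over the lower group, no overlap of single libraries between the 2 groups (which chance gives for 10% of genes) and a gene name beyond the sequence name. It also took 10 study genes (daf-2, daf-16, hsf-1, zip-10, ins-7, pmk-1, skn-1, sod-3, sysm-1 and hsp-16.2), the vitellogenins, and the 2 members with the smallest p in the list's direction for the 8 lists with the smallest camera p. For the interaction the rule took the 5 largest and 5 smallest changes. Other list members given as examples, and the genes of the chromosome V block, were chosen after their values were seen.

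The alternatives set before the data were examined were RLE, upper-quartile and 3-reference-gene scaling (cdc-42, pmp-3 and iscu-1), no filter, a stricter filter of 5 CPM in 3 libraries, a fit of only the 6 libraries compared, the replicate number as a block, DESeq2 1.42.0, a limit of 2-fold, each library left out in turn, and the other gene list tests. Relative to TMM, upper-quartile scaling shifted the median log2 change of all genes by 0.168 for ageing in wild type and 0.128 for ageing in daf-2, and the reference genes shifted it by 0.135 for ageing in wild type, 0.135 for genotype at day 1 and -0.17 for the interaction. Added after seeing the data were a fit with every library thinned to the smallest total, a fit without the day 1 libraries highest in moulting genes, and a fit of the 6 day 9 libraries with the block.

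All 4 groups carry the replicate numbers 1, 2 and 3 in the labels, which do not say that a number marks a shared batch. Across genes, deviations from the group means of same-numbered libraries correlated at 0.36, 0.14 and 0.58 between the genotypes at day 9, so fits with the replicate number as a block are given there beside the fit without it. Day 9 values, standard errors and adjusted p-values are from the fit without the block unless it is named. The correlations at day 1 were 0.23, 0.34 and -0.02. Between ages they were -0.09, 0.01 and -0.18 in wild type and 0.04, -0.01 and -0.31 in daf-2.

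Calculations were tested on data simulated from these samples with 200 changed genes. Neither the broad change seen with age nor correlated genes were simulated. Of genes changed by 0.5, 1 and 2 (log2), 6%, 74.6% and 89.4% were called for ageing in wild type. The interaction gave 1.5%, 40.3% and 83.3%. In wild-type ageing, 8.1% of calls were on unchanged genes. Camera called 0 of 50 random lists and both shifted lists of 20 genes. In other splits of the real libraries it called up to 25 lists. Tables used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9.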

Results

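Gene expression was measured in whole adult C. elegans of the standard laboratory strain N2, taken as wild type, and in animals carrying daf-2(e1370). The daf-2 gene encodes the worm's insulin and insulin-like growth factor receptor, and e1370 is a missense allele that lowers its activity. Both genotypes were sampled at day 1 and day 9 of adulthood, on plates with FUdR, an inhibitor of DNA synthesis that keeps adults from producing progeny. The question was how expression differs between young and old adults of each genotype, and between genotypes at each age. Wild type had total counts of 21406233, 20322128 and 32116409 in the 3 day 1 libraries and 21666006, 22992573 and 21665059 in the 3 day 9 libraries. For daf-2 the totals were 26426598, 23169839 and 24546989 at day 1 and 20991940, 47447136 and 45563330 at day 9. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15523 genes, and log2 changes are given ± SE. Coordinates are on WBcel235.

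The daf-2 transcript (chromosome III, 2994514 to 3040846) was present in every library. Wild type had 109.4, 109.63 and 87.26 CPM at day 1 and 140.18, 102.51 and 128.74 CPM at day 9. In daf-2 animals it was at 131.44, 132.33 and 148.61 CPM at day 1 and 135.11, 149.92 and 181.98 CPM at day 9. None of the 4 comparisons called it (adjusted p = 0.061 to 0.33), and the interaction was -0.10 (adjusted p = 0.8). With upper-quartile scaling it was called for ageing in wild type (0.45, adjusted p = 0.0124) and for genotype at day 1 (0.46, adjusted p = 0.0349). It was also called in both with reference-gene scaling (adjusted p = 0.0379 and 0.0295) and the stricter filter (0.0348 and 0.0309). Because e1370 changes the protein, the level of this mRNA does not check the genotype labels.

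Age was the largest source of difference between libraries. The first principal component of log2 CPM, with 54.5% of the variance, ran from -86.8 to -61.7 in the day 1 libraries and from 47.9 to 85.7 in the day 9 libraries. The second, with 20.7%, separated wild type (32.7 to 60.2) from daf-2 (-60.1 to -30.4).

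**Figure D1:**
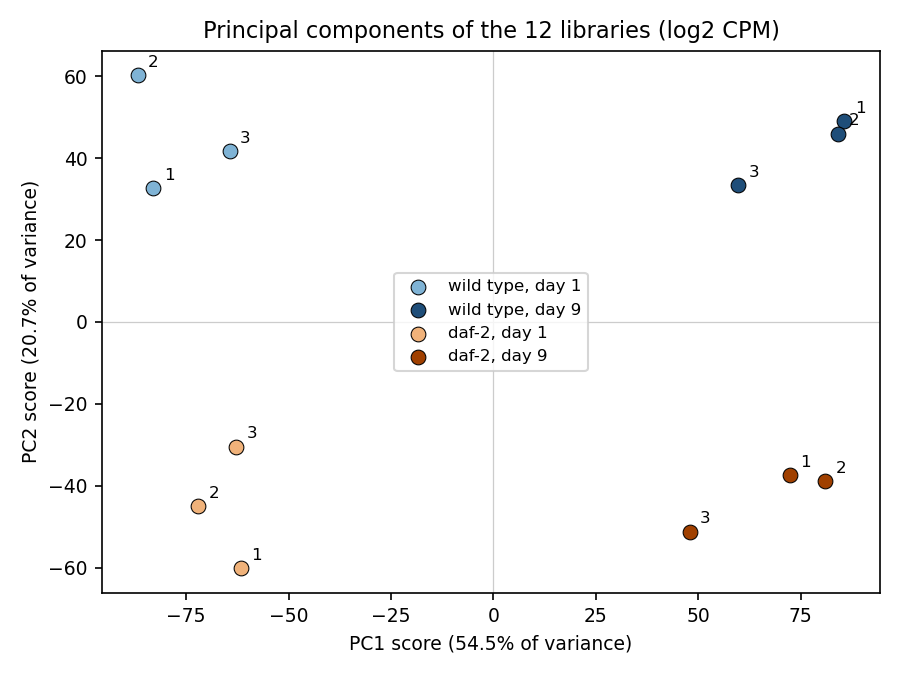
First (54.5% of the variance) against second (20.7%) principal component of log2 CPM for the 12 libraries, coloured by group and labelled with the replicate number. Ages separate along the first component and genotypes along the second.

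Yolk and cuticle transcripts filled a smaller part of the libraries at day 9. In wild type, vitellogenin genes took 11 ± 1.4% of counts at day 1 and 6.5 ± 0.58% at day 9 (SD, n = 3). In daf-2 the values were 14.1 ± 2.9% and 4.31 ± 1.7%. Collagen genes took 2.69 ± 0.51% at day 1 and 0.467 ± 0.015% at day 9 in wild type, and 2.63 ± 0.92% and 0.284 ± 0.089% in daf-2. The genes of the mitochondrial genome took 0.635 ± 0.049% and 0.292 ± 0.037% in wild type and 0.572 ± 0.043% and 0.396 ± 0.052% in daf-2. In each of these 6 comparisons with age the libraries did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow (0.17 adjusted over 32 tests).

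The first comparison asked what changed between day 1 and day 9 in wild type. Named antimicrobial genes rose by up to 214 times, while most genes of cuticle collagens, muscle proteins, yolk proteins and the respiratory chain fell. The lysozyme gene ilys-3 (IV, 2464456 to 2465443) went from 0.215 ± 0.0411 to 47 ± 16.7 CPM (SD, n = 3), a log2 change of 7.74 ± 0.47 (adjusted p = 2.9e-07). Another lysozyme gene, lys-7 (V, 3481432 to 3482600), went from 97.5 ± 28.9 to 5570 ± 713 CPM, a change of 5.83 ± 0.27. The antimicrobial peptide genes cnc-6 (III, 1763522 to 1764902) and cnc-4 (V, 1447195 to 1447707) rose by 6.45 ± 0.48 and 5.70 ± 0.30, and dct-8 (IV, 3895070 to 3895506) and cpt-3 (III, 2082819 to 2088314) by 6.14 ± 0.50 and 5.74 ± 0.46. The cuticle collagen gene col-93 (III, 10984552 to 10985609) had the largest fall among the genes chosen by the rule, from 1390 ± 248 to 1.02 ± 0.184 CPM (log2 change -10.40 ± 0.40, adjusted p = 2.6e-08). It was followed by pud-3 (V, 2324634 to 2325152; -8.32 ± 0.36) and the collagens col-20 (II, 4869670 to 4870791; -7.71 ± 0.43), col-94 (III, 10986808 to 10987873; -7.41 ± 0.41) and col-80 (II, 10707201 to 10708287; -7.15 ± 0.40). In all, 4848 genes rose and 3970 fell, and 3378 and 1344 of them changed by at least 2-fold. With upper-quartile scaling the split was 5849 to 2967.

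Immune genes moved in opposite directions in wild type. Of 59 antimicrobial genes, 36 rose and 8 fell (40 and 9 adjusted over the list alone), and of 18 pathogen-induced genes outside the PMK-1 pathway 12 rose and 3 fell. Of 17 PMK-1 effectors, genes that depend on the p38 MAP kinase PMK-1, 13 fell (14 adjusted over the list alone) and 2 rose. Among the 13 were irg-4 (IV, 12435833 to 12438236), from 295 ± 17.7 CPM at day 1 to 8.05, 17.54 and 23.84 CPM in the day 9 libraries (-4.16 ± 0.29, adjusted p = 8.1e-07), and C17H12.6 (IV, 6821065 to 6822506; -5.27 ± 0.44). The effector sysm-1 (II, 9082626 to 9083193) fell from 70.7 ± 15.2 to 28.5 ± 16 CPM (-1.31 ± 0.37), while the transcript of pmk-1 itself (IV, 8148794 to 8151266) rose by 0.71 ± 0.12 (adjusted p = 0.00042). Of 117 C-type lectin genes 42 rose and 27 fell. For this and the lists that follow, counts adjusted over the list alone were equal to the first counts unless given.

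Of 27 insulin-like peptide genes 11 rose in wild type with age and 1 fell. The study gene ins-7 (IV, 9682011 to 9682845) rose from 1.67 ± 1.36 to 80.9 ± 16.9 CPM (5.5 ± 0.44, adjusted p = 1.8e-06). Of 28 components of insulin signalling 8 rose and 8 fell, against 11 and 7 with upper-quartile or reference-gene scaling. The FOXO transcription factor gene daf-16 (I, 10750498 to 10776703) had 138 ± 14.9 CPM at day 1 and 130 ± 11.8 at day 9 (-0.08, adjusted p = 0.55). Of 25 DAF-16 targets 12 rose and 5 fell, and of 17 DAF-16-repressed genes 3 rose and 6 fell. The DAF-16 target sod-3 (X, 17092753 to 17094306), a mitochondrial superoxide dismutase gene, fell by 0.72 on the log2 scale (adjusted p = 0.04), a call lost without wild-type day 1 replicate 1 (adjusted p = 0.105), 2 (0.081) or 3 (0.0503) or wild-type day 9 replicate 1 (0.0971) or 3 (0.127), with log2 changes of -0.81 to -0.59. It was also lost with upper-quartile (-0.55, adjusted p = 0.106) or reference-gene scaling (adjusted p = 0.0782) and with the stricter filter (-0.64, 0.0666). The bZIP transcription factor gene zip-10 (V, 11650079 to 11650762) rose from 19.7 ± 8.11 to 43.7 ± 1.42 CPM (1.14 ± 0.32, adjusted p = 0.01).

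Protein folding and stress genes were mixed. Of 33 cytosolic heat shock genes 6 rose and 15 fell (16 adjusted over the list alone): hsp-16.2 (V, 1804334 to 1804957) rose by 2.40 ± 0.58 (adjusted p = 0.0041) and hsp-70 by 2.81, while the constitutive chaperone genes hsp-1 and hsp-110 fell by 1.24 and 1.55 on the log2 scale. The heat shock factor gene hsf-1 (I, 11953507 to 11963085) fell from 93.8 ± 9.54 to 67.0 ± 2.14 CPM (-0.48 ± 0.10, adjusted p = 0.0018). Of 22 chaperones of the endoplasmic reticulum and mitochondria 9 rose and 7 fell. Of 27 antioxidant genes 8 rose and 13 fell (14 adjusted over the list alone). The stress transcription factor gene skn-1 (IV, 5651039 to 5660384) fell by 0.38 on the log2 scale (adjusted p = 0.021), a call lost without wild-type day 1 replicate 2 or wild-type day 9 replicate 2 (-0.28 and -0.32, adjusted p = 0.0843 for each) and with upper-quartile (-0.20) or reference-gene scaling (-0.23). Among detoxification genes, 15 of 34 glutathione S-transferases fell and 3 rose, 23 of 63 UDP-glycosyltransferases fell and 15 rose, and 16 of 62 cytochrome P450 genes fell and 21 rose.

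Most genes of the respiratory chain and the proteasome fell in wild type. Of 12 protein-coding genes of the mitochondrial genome all 12 fell, among them WBGene00010967 (MtDNA, 11691 to 13272), from 515 ± 67.4 to 168 ± 21.4 CPM (-1.62 ± 0.13, adjusted p = 1.8e-06), and WBGene00000829 (MtDNA, 4504 to 5621; -1.85 ± 0.15). Of 40 nuclear genes of the respiratory chain 33 fell and 0 rose (34 and 0 adjusted over the list alone), among them sdha-2 (I, 10683270 to 10685587), a succinate dehydrogenase subunit gene, from 221 ± 22.7 to 84.6 ± 4.93 CPM (-1.38 ± 0.11), and ndub-5 (-1.0 ± 0.09). Of 33 proteasome genes 30 fell (32 adjusted over the list alone), with pas-2 (V, 10770368 to 10771351) at -1.17 ± 0.11 and rpt-4 (II, 42207 to 46216) at -0.86 ± 0.09. Of 82 ribosomal protein genes 55 fell (57 adjusted over the list alone), against 37 with upper-quartile and 41 with reference-gene scaling, with rps-2 (IV, 7925298 to 7926391) at -1.38 ± 0.15 and rpl-7A at -1.45 ± 0.17, and of 22 ribosome biogenesis genes 15 fell and 3 rose (11 and 3 with either of these scalings). The share of counts of the ribosomal protein genes changed by -1.34 percentage points, and the libraries overlapped. The exact two-sided permutation test gave p = 0.2 (0.29 adjusted over 32 tests). In fatty acid synthesis 10 of 21 genes fell and 3 rose, and in lipid breakdown 12 of 24 fell and 5 rose (12 and 6 adjusted over the list alone). In the list of trehalose, glyoxylate and gluconeogenesis genes 14 of 29 fell and 3 rose (5 rose with upper-quartile scaling). Of 45 autophagy and lysosome genes 21 fell and 14 rose. Their median change of -0.17 turned to 0.01 with upper-quartile scaling.

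Tissue markers in wild type followed several courses. Of 29 body wall muscle genes 23 fell and 0 rose, among them the troponin T gene tnt-2 (X, 8721546 to 8723550), from 230 ± 75.3 to 8.44 ± 1.26 CPM (-4.77 ± 0.30), and the myosin light chain gene mlc-2 (X, 17455792 to 17456586; -2.82 ± 0.23). Of 124 cuticle collagens 68 fell and 12 rose (69 and 12 adjusted over the list alone), with col-155 (V, 11388852 to 11389876) at -2.90 ± 0.13. Of 21 hypodermis and seam genes 11 fell and 1 rose (11 and 2 adjusted over the list alone, and 4 rose with upper-quartile scaling), of 22 intestinal genes 11 fell and 3 rose (12 and 3), and of 22 moulting-cycle genes 2 fell and 3 rose. Of 37 neuronal genes 14 rose and 2 fell (13 and 2 adjusted over the list alone), of 17 pharyngeal genes 2 rose and 1 fell, and of 10 coelomocyte and other small-cell genes 2 rose and 4 fell, against 4 and 2 with upper-quartile scaling. In the germ line lists 25 of 53 oocyte and germline genes fell and 5 rose (8 with upper-quartile or reference-gene scaling), 16 of 60 sperm genes rose and 0 fell (12 and 0 adjusted over the list alone), and 8 of 24 zygotic genes fell and 4 rose. Before TMM scaling, the oocyte and germline genes' share of counts rose from 2.43 ± 0.17% to 2.79 ± 0.15% (SD, n = 3). TMM factors, 0.821 to 0.911 at day 1 and 1.102 to 1.136 at day 9, lower the day 9 levels. The libraries did not overlap (exact two-sided permutation test, p = 0.1, the smallest possible, and 0.17 adjusted over 32 tests). The median level of the sperm genes, relative to their mean over the 12 libraries, was -0.24, 0.46 and 0.36 log2 units in the wild-type day 1 libraries and 1.82, 1.55 and -0.05 in those of day 9, so that day 9 replicate 3 lay within the day 1 range. Replicate 3 was also the lowest at day 9 in daf-2 (0.6, 0.08 and -1.25). Of 51 replication-dependent histone genes 10 rose (17 with upper-quartile scaling) and 3 fell, and 1 of 6 ribosomal RNA genes, WBGene00014454, rose.

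Of the 6 vitellogenin genes, which encode yolk proteins, 4 fell in wild type and 0 rose. These were vit-1 (X, 7727889 to 7733168), from 5540 ± 1300 to 195 ± 9.23 CPM (-4.83 ± 0.35), vit-3 (X, 3567355 to 3572549; -6.21 ± 0.49), vit-4 (X, 3558769 to 3563965; -5.48 ± 0.55) and vit-6 (IV, 8261157 to 8266459), from 32900 ± 4280 to 10800 ± 1630 CPM (-1.61 ± 0.33, adjusted p = 0.0013). The most abundant copies at day 9 were vit-2 (X, 5101042 to 5106169), with 33800 ± 1920 and 22200 ± 2780 CPM (-0.61 ± 0.33, adjusted p = 0.13, and 0.0185 in a fit of only the 6 libraries compared), and vit-5 (X, 3403471 to 3408603), with 31300 ± 2390 and 24500 ± 2070 CPM (-0.35 ± 0.30, adjusted p = 0.33). At the preset correlation camera called 20 of the 37 lists, with an estimated one 0 (lowest adjusted p = 0.56), and fry called 24. The lists are thus described by their member counts, against 31.2% of all genes higher and 25.6% lower. The signs of median, mean and camera test differed for 4 lists: insulin signalling components, endoplasmic reticulum and mitochondrial chaperones, moulting-cycle genes and coelomocyte markers.

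The second comparison asked what changed between day 1 and day 9 in daf-2. Most collagen, muscle, yolk and intestinal genes fell, and antimicrobial genes were divided between rises and falls. The largest rises among the genes chosen by the rule were clx-1 (IV, 7734648 to 7736324), from 0.822 ± 0.426 to 1530 ± 991 CPM (SD, n = 3; 10.85 ± 0.67, adjusted p = 4.4e-07), dao-6 (III, 9735263 to 9736201), from 0.336 ± 0.11 to 54.4 ± 15.7 CPM (7.29 ± 0.36), and pitr-4 (V, 9658862 to 9661614), from 0.315 ± 0.0571 to 23.2 ± 6.18 CPM (6.18 ± 0.29). They were followed by fbxa-165 (4.65 ± 0.38) and fipr-24 (I, 14157611 to 14158078; 4.25 ± 0.21). The changes of clx-1 and dao-6 with age were not called as different between the genotypes (interaction adjusted p = 0.16 and 0.18). At the other end, col-93 fell from 1480 ± 557 to 0.157 ± 0.141 CPM (-13.46 ± 0.47, adjusted p = 5.2e-09), followed by pud-3 (-9.95 ± 0.41), col-94 (-8.77 ± 0.42), col-20 (-7.91 ± 0.43) and pud-4 (V, 2326678 to 2327282; -7.15 ± 0.49). In all, 3395 genes rose and 3330 fell, 2019 and 1515 of them by at least 2-fold, and the split was 4351 to 2602 with upper-quartile scaling.

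In daf-2, 17 of 59 antimicrobial genes rose with age and 21 fell (22 adjusted over the list alone). Of 17 PMK-1 effectors 12 fell (13 adjusted over the list alone) and 0 rose: irg-4 changed by -4.17 ± 0.32, C17H12.6 by -5.33 ± 0.47, and sysm-1 fell from 45.6 ± 4.44 to 3.92 ± 1.85 CPM (-3.58 ± 0.41, adjusted p = 4.1e-05). Among C-type lectins 38 of 117 fell and 21 rose (38 and 22 adjusted over the list alone), and of 18 pathogen-induced genes 5 rose and 3 fell. Of 27 insulin-like peptide genes 6 rose and 5 fell, and ins-7 had 1.09 ± 0.112 CPM at day 1 and 0.511 ± 0.219 at day 9 (-1.1 ± 0.52, adjusted p = 0.1, and 0.0436 with DESeq2). Of 17 DAF-16-repressed genes 8 fell and 0 rose, and of 25 DAF-16 targets 13 rose and 6 fell (14 and 6 adjusted over the list alone). The sod-3 transcript, at 52.4 ± 3.4 and 58.2 ± 24.9 CPM (0.15, adjusted p = 0.63), hsf-1 (-0.20, adjusted p = 0.12) and skn-1 (0.13, adjusted p = 0.4) were not called. Without daf-2 day 1 replicate 1, hsf-1 was called (-0.30, adjusted p = 0.0308). The interactions of these 3 genes were not called either (adjusted p = 0.174, 0.261 and 0.104). Expression of hsp-16.2 rose from 2.14 ± 1.27 to 8.05 ± 1.08 CPM (1.91 ± 0.55, adjusted p = 0.015).

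The calls of 3 regulator genes in daf-2 were lost when single libraries were left out. The daf-16 transcript rose from 140 ± 13.6 to 180 ± 14.5 CPM (0.36 ± 0.11, adjusted p = 0.022), a call lost without daf-2 day 1 replicate 1 (0.28, adjusted p = 0.0833) or daf-2 day 9 replicate 2 (0.33, 0.0739) or 3 (0.33, 0.067), and its interaction was not called (0.45, adjusted p = 0.118). The rise of pmk-1 (0.37 ± 0.12, adjusted p = 0.026) was lost without daf-2 day 1 replicate 2 (0.28, adjusted p = 0.104) or 3 (0.36, 0.0556) or daf-2 day 9 replicate 2 (0.33, 0.0902) or 3 (0.37, 0.0601), and with reference-gene scaling (adjusted p = 0.0742). Expression of zip-10 fell from 42.2 ± 14 to 19.7 ± 6.97 CPM (-1.11 ± 0.32, adjusted p = 0.016), which was lost without daf-2 day 1 replicate 1 (-0.81, adjusted p = 0.0729) or daf-2 day 9 replicate 2 (-0.86, 0.0595).

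Most collagen, muscle, intestinal and fatty acid synthesis genes fell in daf-2. Of 124 cuticle collagens 72 fell and 9 rose (74 and 10 adjusted over the list alone), of 29 body wall muscle genes 22 fell and 0 rose, and of 22 intestinal genes 18 fell and 0 rose (18 and 1 adjusted over the list alone). Examples were col-155 (-3.62 ± 0.13), tnt-2 (-4.90 ± 0.30), mlc-2 (-3.44 ± 0.23) and the intestinal actin gene act-5 (III, 13604412 to 13606066), from 756 ± 159 to 66.8 ± 29.2 CPM (-3.50 ± 0.31, adjusted p = 5.1e-06). Of 21 fatty acid synthesis genes 14 fell and 1 rose, among them the desaturase gene fat-7 (V, 7151353 to 7153146), from 24.4 ± 1.39 to 0.506 ± 0.125 CPM (-5.58 ± 0.26), and elo-9 (-2.06 ± 0.25), and of 24 lipid breakdown genes 15 fell and 4 rose (15 and 5 adjusted over the list alone, and 2 rose with reference-gene scaling). All 6 vitellogenin genes fell: vit-1 (-4.37 ± 0.34), vit-2 (-1.65 ± 0.33), vit-3 (-6.56 ± 0.50), vit-4 (-6.05 ± 0.57), vit-5 (-2.25 ± 0.31) and vit-6 (-1.78 ± 0.33). Of 12 protein-coding genes of the mitochondrial genome 12 fell, among them WBGene00010963 (MtDNA, 6506 to 7808; -1.06 ± 0.12) and WBGene00010966 (MtDNA, 11356 to 11691; -2.08 ± 0.26). Of the nuclear respiratory chain genes 25 of 40 fell and 0 rose (29 and 2 adjusted over the list alone, and 3 rose with upper-quartile scaling), among them asg-2 (-1.23 ± 0.12) and sdha-2 (-1.0 ± 0.11). Of 33 proteasome genes 14 fell and 0 rose (15 and 0 adjusted over the list alone). With upper-quartile scaling 8 fell and 2 rose. Of 82 ribosomal protein genes 27 fell and 1 rose (23 and 1 adjusted over the list alone). With upper-quartile scaling 19 of them fell, and with reference-gene scaling 35. Of 63 UDP-glycosyltransferases 33 fell and 6 rose (33 and 8 adjusted over the list alone), of 34 glutathione S-transferases 20 fell and 4 rose, and of 51 histone genes 18 rose and 1 fell (18 and 0). Camera called 19 of the 37 lists and 0 with an estimated correlation (lowest adjusted p = 0.44), and fry called 20. Of all genes 21.9% rose and 21.5% fell. The signs of median, mean and test differed for 4 lists: pathogen-induced genes, cytosolic heat shock genes, cytochrome P450 genes and coelomocyte markers.

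**Figure D2:**
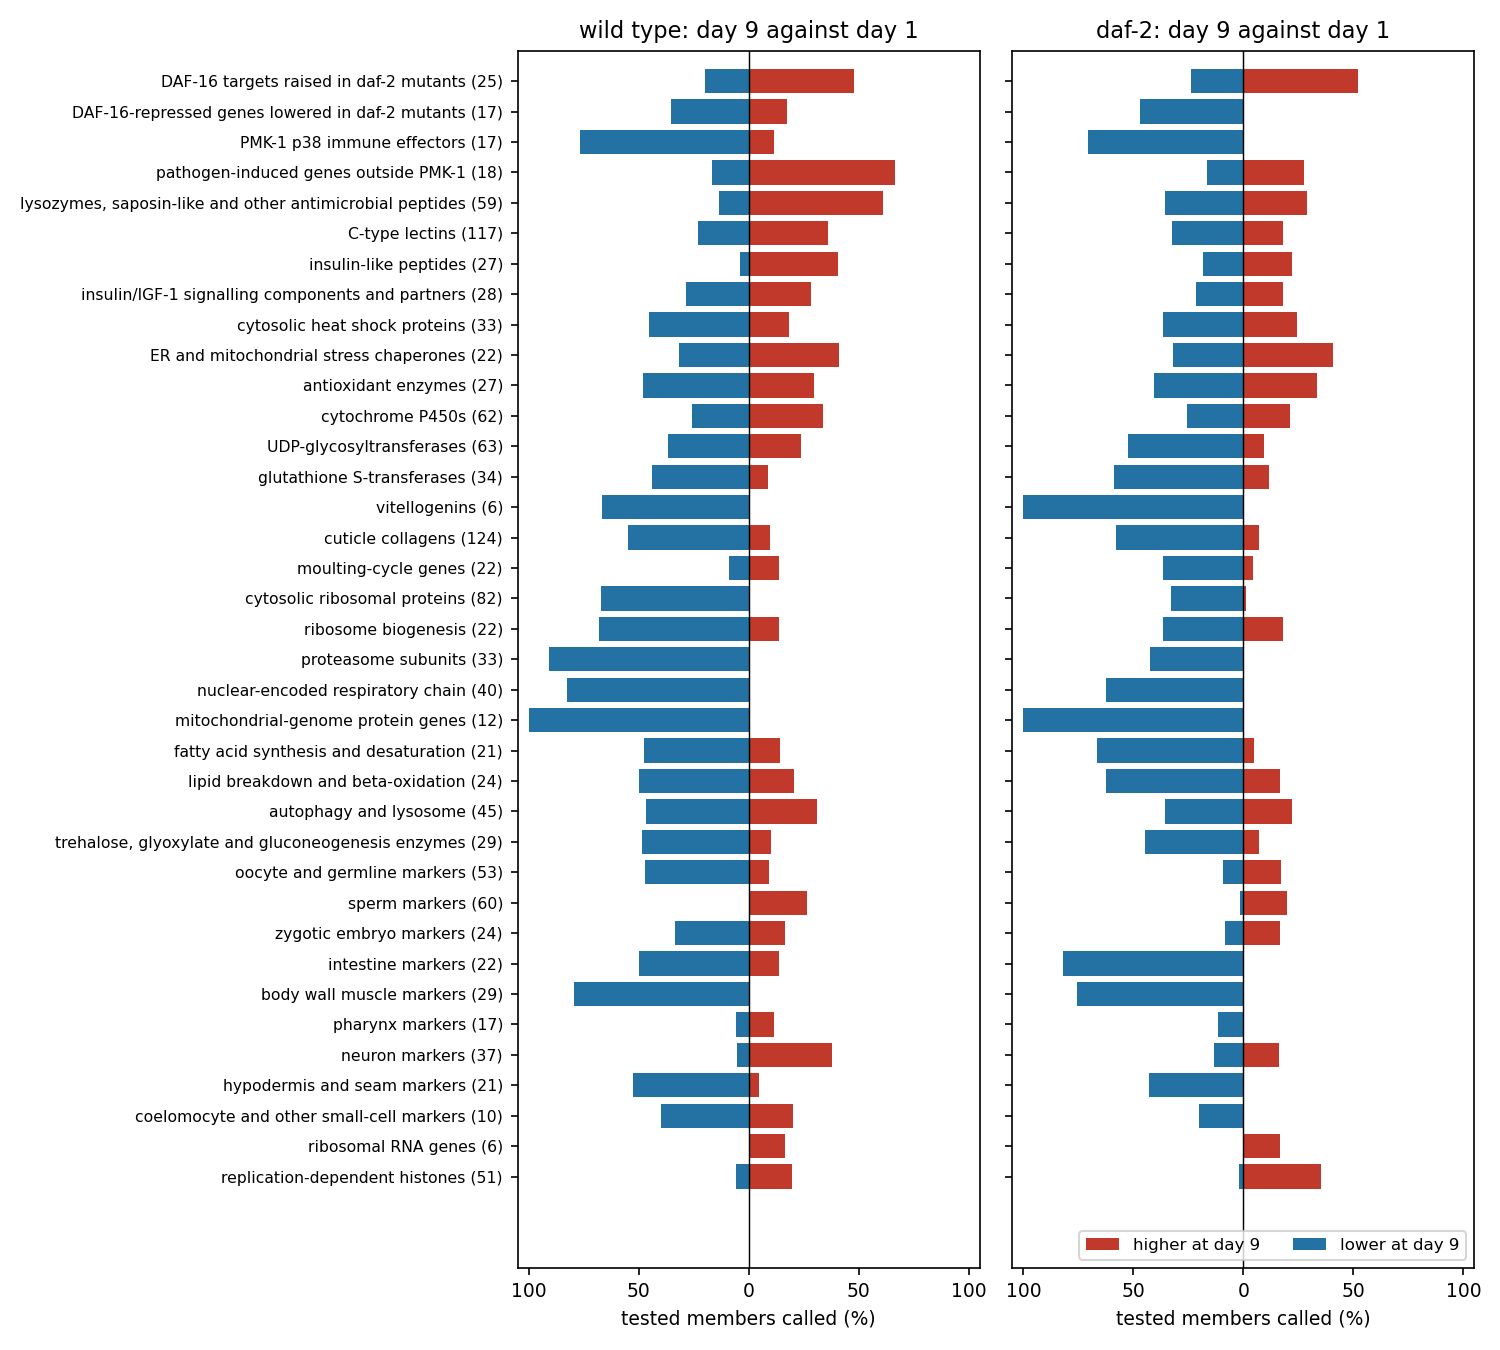
Percent of the tested members of each of the 37 gene lists called higher (red, to the right) or lower (blue, to the left) at day 9 than at day 1, in wild type (left panel) and daf-2 (right panel), with the number tested in parentheses. Antimicrobial genes went mostly up in wild type (36 of 59 higher, 8 lower) and both ways in daf-2 (17 higher, 21 lower), while muscle genes went down in both (23 and 22 of 29 lower).

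Most genes that changed with age in both genotypes moved the same way. A total of 2710 genes rose in both, against 1060 for independent lists of those sizes, and 2417 fell in both, against 852. Opposite calls were fewer than for independent lists, with 81 genes that rose in wild type and fell in daf-2 (1040) and 8 that did the reverse (868). Across the 15523 genes, which are not independent replicates, the 2 sets of log2 changes had Pearson's r of 0.79 and Spearman's rho of 0.78.

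The third comparison asked how daf-2 differed from wild type at day 1. Most DAF-16 targets, a list of genes already reported as raised in daf-2 mutants, were higher in daf-2. So were part of the antimicrobial, insulin-like peptide and neuronal genes, while part of the proteasome and germline genes were lower by small amounts. The largest differences among the genes chosen by the rule were those of the cathepsin B-like protease gene cpr-2 (V, 16532936 to 16534100), at 0.181 ± 0.135 CPM in wild type and 67.7, 73.2 and 357.69 CPM in the 3 daf-2 libraries (10.02 ± 1.01, adjusted p = 5.6e-05), icmt-1 (I, 4901918 to 4903264), at 0.505 ± 0.333 and 50.5 ± 3.0 CPM (SD, n = 3; 6.53 ± 0.36), and clc-24 (III, 1010037 to 1011400; 6.01 ± 0.40). The neighbouring genes asp-18 (V, 18730174 to 18731679; 6.65 ± 1.61, adjusted p = 0.017) and scl-19 (V, 18731991 to 18732772; 6.18 ± 1.6, adjusted p = 0.028) owed their size to daf-2 day 1 replicate 3. Without it asp-18 was at 3.40 (adjusted p = 0.0733) and scl-19 at 3.17 (adjusted p = 0.0796). Without wild-type day 1 replicate 3 asp-18 was at 11.84 (adjusted p = 0.0439), and its call was also lost without wild-type day 1 replicate 2 (adjusted p = 0.0736), that of scl-19 without wild-type day 1 replicate 1 (0.0599), 2 (0.107) or 3 (0.072). Lower in daf-2 were the C-type lectin gene clec-10 (II, 402678 to 404180; -6.50 ± 0.34), the lysozyme gene ilys-5 (X, 6533490 to 6536840), at 404 ± 8.9 and 6.72 ± 3.62 CPM (-5.91 ± 0.46), dod-24 (IV, 12940106 to 12941354; -5.65 ± 0.89), dod-22 (IV, 12965374 to 12967392; -4.77 ± 0.41) and irg-5 (V, 13737010 to 13738474; -4.24 ± 0.55). In all, 1600 genes were higher in daf-2 and 786 lower, and 936 and 228 differed by at least 2-fold.

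These counts depended on the scaling and on single libraries. The split was 1481 to 1206 with RLE scaling and 1960 to 302 with the reference genes. Without wild-type day 1 replicate 2 it was 920 to 239, without daf-2 day 1 replicate 1 it was 879 to 248, and without daf-2 day 1 replicate 2 the lower count was 474.

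Of 25 DAF-16 targets 18 were higher in daf-2 at day 1 and 0 lower (21 and 1 adjusted over the list alone). Since these genes were listed for being raised in daf-2 mutants, this direction was known beforehand. The list was called by camera (adjusted p = 7.2e-13, but 0.069 with an estimated correlation). Examples were sod-3, at 6.73 ± 0.733 CPM in wild type and 52.4 ± 3.4 in daf-2 (2.96 ± 0.27, adjusted p = 2.8e-05), dod-6 (III, 10197716 to 10198352), at 7.08 ± 2.38 and 228 ± 17.5 CPM (4.99 ± 0.33), and the long noncoding RNA tts-1 (X, 1504131 to 1504841), at 26.6 ± 6.68 and 314 ± 55.6 CPM (3.55 ± 0.21). Neither daf-16 (0.02, adjusted p = 0.92), hsf-1 (-0.09, 0.54), pmk-1 (0.16, 0.37), skn-1 (-0.32, 0.097), ins-7 (-0.72, 0.31), sysm-1 (-0.63, 0.25) nor hsp-16.2 (0.86, 0.33) was called. Of these, skn-1 was called with DESeq2 (-0.39, adjusted p = 0.0434) and without daf-2 day 1 replicate 3 (-0.43, 0.0463), and hsp-16.2 without the day 1 libraries highest in moulting genes (2.12, adjusted p = 0.0135). Expression of zip-10 was higher in daf-2 (1.09 ± 0.32, adjusted p = 0.04), a call lost without wild-type day 1 replicate 1 (0.81, adjusted p = 0.0786) or 2 (1.11, 0.112) or daf-2 day 1 replicate 1 (0.79, 0.176). It was also lost in a fit of only the 6 libraries compared (1.11, 0.0777) and without the libraries highest in moulting genes (0.91, 0.0761). Of 27 insulin-like peptide genes 10 were higher and 0 lower (11 and 0 adjusted over the list alone), among them ins-10 (V, 14033949 to 14034396; 4.1 ± 0.54) and ins-22 (III, 10026289 to 10026686; 3.02 ± 0.43). Of 37 neuronal genes 10 were higher and 0 lower (15 and 0 adjusted over the list alone), among them the synaptic genes unc-13 (I, 7422785 to 7454116), at 6.83 ± 1.56 and 27.1 ± 1.57 CPM (1.98 ± 0.24), and cla-1 (IV, 7588931 to 7628238; 1.82 ± 0.31).

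Of 59 antimicrobial genes 19 were higher in daf-2 at day 1 and 3 lower (28 and 6 adjusted over the list alone), and of 17 PMK-1 effectors 3 were higher and 8 lower (6 and 8), among them irg-4, at 295 ± 17.7 CPM in wild type and 24 ± 2.54 in daf-2. Of 62 cytochrome P450 genes 15 were higher and 7 lower (20 and 8 adjusted over the list alone, and 3 lower with reference-gene scaling), and of 63 UDP-glycosyltransferases 15 were higher and 8 lower (21 and 8, and 4 lower with reference-gene scaling). Of 33 proteasome genes 11 were lower and 0 higher (26 and 0 adjusted over the list alone). The lower count was 17 with RLE or upper-quartile and 2 with reference-gene scaling. The proteasome genes pbs-3 (-0.41 ± 0.10, adjusted p = 0.02) and pas-1 (-0.44 ± 0.11, adjusted p = 0.021) lost their calls without wild-type day 1 replicate 2 (adjusted p = 0.082 and 0.089) or daf-2 day 1 replicate 1 (0.0689 and 0.0899). In these fits pas-1 was at -0.33 and -0.37. Both calls were also lost in a fit of only the 6 libraries compared (adjusted p = 0.1 and 0.101). Of 53 oocyte and germline genes 13 were lower and 0 higher (29 and 1 adjusted over the list alone), among them zif-1 (III, 9002779 to 9004839), at 128 ± 16.7 and 79.6 ± 17.6 CPM (-0.68 ± 0.14, adjusted p = 0.0075). With RLE scaling 20 germline genes were lower, and with upper-quartile scaling 18. With reference-gene scaling 1 of those 13 was still lower, as it was without wild-type day 1 replicate 2 or daf-2 day 1 replicate 1. Without wild-type day 1 replicate 3 the number was 6, and without daf-2 day 1 replicate 2 it was 4. Of 60 sperm genes 4 were lower and 0 higher (0 and 0 adjusted over the list alone), and of 40 nuclear respiratory chain genes 4 were lower and 0 higher (0 and 0). With RLE scaling 8 were lower in each of these lists, and with reference-gene scaling 1 and 0. No vitellogenin gene was called (adjusted p = 0.072 for vit-1, 0.14 for vit-6, 0.2 for vit-2 and 0.48 to 0.98 for vit-3, vit-4 and vit-5). The alternatives that called vit-1 were DESeq2 (-0.91, adjusted p = 0.0135) and no filter (-0.87, 0.0489).

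Moulting-cycle and collagen genes varied between libraries within the day 1 groups. Of 22 moulting-cycle genes 1 was higher in daf-2 and 0 lower, and of 124 collagens 10 were higher and 4 lower (9 and 3 adjusted over the list alone). The median level of the moulting-cycle genes, relative to their mean over the 12 libraries, was 0.59, -0.5 and -0.28 log2 units in the wild-type day 1 libraries and 0.4, 0.04 and 0.54 in those of daf-2. Without the highest library of each group, a fit chosen after seeing the data, 2250 genes were higher and 1220 lower in daf-2. Camera called 14 lists at day 1 and 0 with an estimated correlation, and fry called 6. Signs of median, mean and test differed for the cytosolic heat shock, mitochondrial genome and pharyngeal lists.

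The fourth comparison asked how the genotypes differed at day 9. Most DAF-16 targets were again higher in daf-2, and part of the antimicrobial, C-type lectin and pathogen-induced genes were lower. The gene ins-7 was at 80.9 ± 16.9 CPM in wild type and 0.511 ± 0.219 in daf-2 (SD, n = 3; -7.31 ± 0.48, adjusted p = 3.2e-06). Lysozyme gene ilys-5 was at 178 ± 79.8 and 0.102 ± 0.0891 CPM (-10.45 ± 0.63), and clec-10 at 11 ± 1.72 and 0.071 ± 0.0271 CPM (-7.12 ± 0.34). The cathepsin B-like protease genes cpr-5 (V, 1132598 to 1134036; -6.21 ± 0.64) and cpr-1 (V, 11975551 to 11976756), at 288 ± 71.5 and 4.64 ± 1.53 CPM (-5.97 ± 0.48), were lower too. Higher in daf-2 were clx-1, at 0.569 ± 0.397 and 1530 ± 991 CPM (11.39 ± 0.68), cpr-2 (5.99 ± 0.71), the saposin-like gene spp-20 (V, 6557615 to 6558203; 5.73 ± 0.65), dao-6 (5.66 ± 0.32) and the acetylcholine receptor subunit gene unc-38 (I, 4897620 to 4900974), at 2.77 ± 0.328 and 40.0 ± 3.07 CPM (3.85 ± 0.16). In all, 704 genes were higher and 971 lower in daf-2. With the replicate number as a block, the counts were 788 and 983 over the 12 libraries, and 1420 and 2077 in a fit of the 6 day 9 libraries chosen after seeing the data (1150 and 1215 without the block). Leaving out wild-type day 9 replicate 1, 2 or 3 brought the higher count to 418, 399 and 455, and the lower count fell to 633 without wild-type day 9 replicate 2 and to 622 without daf-2 day 9 replicate 2.

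Of 59 antimicrobial genes 29 were lower in daf-2 at day 9 and 3 higher (36 and 5 adjusted over the list alone), with ilys-2 (IV, 2467678 to 2468879) at 8.84 ± 2.1 and 0.23 ± 0.0811 CPM (-5.32 ± 0.50). The list was called by camera (adjusted p = 4.6e-14, but 0.45 with an estimated correlation). Of 117 C-type lectin genes 30 were lower and 10 higher (36 and 16 adjusted over the list alone), among them clec-146 (II, 13590641 to 13593774), at 151.84, 182.87 and 177.08 CPM in wild type and 49.35, 47.95 and 56.48 in daf-2 (-1.73 ± 0.13). Of 18 pathogen-induced genes 7 were lower and 0 higher (9 and 0 adjusted over the list alone), of 17 PMK-1 effectors 8 were lower and 1 higher (11 and 1), and of 17 DAF-16-repressed genes 7 were lower and 0 higher (9 and 0). Examples were irg-4 (-3.63 ± 0.32), sysm-1 (-2.90 ± 0.41, adjusted p = 0.00057) and dod-22 (-5.30 ± 0.58). Of 25 DAF-16 targets 17 were higher and 1 lower (18 and 3 adjusted over the list alone), with sod-3 at 4.06 ± 0.886 and 58.2 ± 24.9 CPM (3.84 ± 0.28, adjusted p = 6.4e-06) and dod-6 at 55.5 ± 12 and 411 ± 169 CPM (2.89 ± 0.29).

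Of 22 intestinal genes 7 were lower in daf-2 at day 9 and 1 higher (9 and 2 adjusted over the list alone), and of 21 fatty acid synthesis genes 6 were lower and 4 higher (6 and 5), with fat-7 at 12.9 ± 2.66 and 0.506 ± 0.125 CPM (-4.66 ± 0.26). Of the vitellogenins vit-5 was lower, at 24500 ± 2070 and 5620 ± 2440 CPM (-2.12 ± 0.31, adjusted p = 0.00075), and the other 5 were not called (adjusted p = 0.26 to 0.5). Of 12 protein-coding genes of the mitochondrial genome 3 were higher and 0 lower (6 and 0 adjusted over the list alone), with ND1 (MtDNA, 1763 to 2635) at 127 ± 9.39 and 205 ± 7.63 CPM (0.69 ± 0.11). Another of them, WBGene00010965 (MtDNA, 9649 to 10348; 0.64 ± 0.16), lost its call without wild-type day 9 replicate 1 (adjusted p = 0.0713) or 3 (0.52, 0.0908) or daf-2 day 9 replicate 1 (0.54, 0.0871). Of 60 sperm genes 4 were lower and 0 higher (1 and 0 adjusted over the list alone), among them ssp-37 (I, 12561040 to 12561560; -1.53 ± 0.29). In the fit of the 6 day 9 libraries with the replicate block, which takes up the low level of replicate 3 in both genotypes, 46 of the 60 were lower. The number was 4 without the block and 4 with it over the 12 libraries. Heat shock genes were higher for 4 of 33 and lower for 0, and antioxidant genes for 5 of 27 and 0. The daf-16 transcript was higher in daf-2 (0.47 ± 0.11, adjusted p = 0.02), a call lost without wild-type day 9 replicate 2 (0.39, adjusted p = 0.102) or 3 (0.48, 0.0537) or daf-2 day 9 replicate 2 (0.43, 0.0704) or 3 (0.43, 0.0644). Expression of zip-10 was lower (-1.16 ± 0.32, adjusted p = 0.038), a call lost without wild-type day 9 replicate 1 (-1.17, adjusted p = 0.0887), 2 (-1.13, 0.104) or 3 (-1.17, 0.0747) or daf-2 day 9 replicate 2 (-0.91, 0.124) or 3 (-1.18, 0.0818). Neither hsf-1 (0.19, 0.29), pmk-1 (-0.18, 0.39), skn-1 (0.19, 0.37) nor hsp-16.2 (0.36, 0.72) was called. Camera called 14 lists and 0 with an estimated correlation (lowest adjusted p = 0.2), and fry called 8. Signs of median, mean and test differed for 6 lists: insulin-like peptides, collagens, fatty acid synthesis, lipid breakdown, autophagy and lysosome, and pharynx.

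A total of 396 genes were higher in daf-2 at both ages, against 73 for independent lists, and 155 were lower at both, against 49. Opposite calls numbered 72 (higher at day 1 and lower at day 9, against 100) and 4 (the reverse, against 36). Across genes, the log2 differences at the 2 ages had Pearson's r of 0.56 and Spearman's rho of 0.37.

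Among the genes higher in daf-2 at both ages were 18 tested genes in 1 stretch of chromosome V (17339084 to 17551209), found after seeing the data. Over this 212 kb the 6 wild-type libraries had 0, 2, 2, 1, 1 and 0 counts, and the 6 daf-2 libraries had 28771 in all, with 1776 in the lowest. The annotation places 81 genes there, 41 protein-coding and 35 pseudogenes. Examples are skr-5 (0 wild-type and 1894 daf-2 counts), lsy-27 (1 and 6452), fbxb-7 (1 and 3551) and fbxa-189 (1 and 1713). The flanking genes were picked for having wild-type counts. For sdz-16 (17326449 to 17327967) wild type had 56 and daf-2 182 counts, and for C38D9.2 (17567150 to 17571742) 3303 and 10371.

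**Figure D3:**
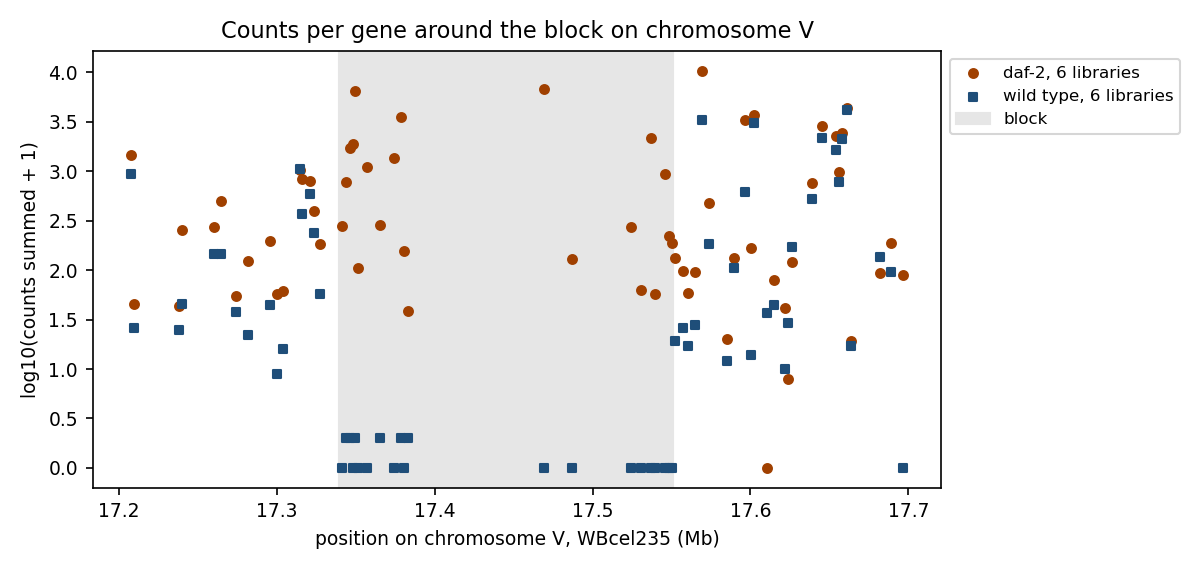
Counts per gene, summed over the 6 libraries of each genotype and shown as log10 of the count plus 1, by gene position on chromosome V in Mb, with daf-2 as circles, wild type as squares and the block shaded. Inside the block the wild-type libraries have 6 counts in all and the daf-2 libraries 28771, while genes on both sides have counts in both genotypes.

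The last comparison asked which changes with age differed between the genotypes, tested as the interaction. Part of the antimicrobial, C-type lectin, insulin-like peptide and intestinal genes had a lower log2 change with age in daf-2. This was a smaller rise, a larger fall or a reversal. The interaction was negative for 732 genes, meaning that the log2 change was lower in daf-2, and positive for 89, with 625 and 41 beyond 2-fold. Of the 732 genes, 306 rose in wild type and were not called in daf-2, 154 rose in both, 140 fell in daf-2 and were not called in wild type, 81 rose in wild type and fell in daf-2, and 51 fell in both. Both counts moved with single libraries. Without wild-type day 9 replicate 2 they were 404 and 29, and without daf-2 day 1 replicate 3 they were 1097 and 233. The stricter filter gave 831 and 225, and DESeq2 gave 1157 and 449.

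The most negative interactions among the genes chosen by the rule were those of ins-7 (-6.60 ± 0.67, adjusted p = 0.00025) and the protease gene cpr-4 (V, 6614674 to 6615851), which had 25.7 ± 5.79 and 121 ± 56.1 CPM at day 1 and day 9 in wild type and 146 ± 60.5 and 7.34 ± 6.52 in daf-2 (SD, n = 3; -6.60 ± 0.80, adjusted p = 0.00089). The arginine kinase gene argk-1 (V, 16103894 to 16105952) had 0.92 ± 0.147 and 14.3 ± 5.99 CPM in wild type and 4.4 ± 1.69 and 1.21 ± 0.631 in daf-2 (-5.87 ± 0.62). The fatty acid and retinol binding protein gene far-3 (V, 12996787 to 12997522) had 29.9 ± 2.85 and 484 ± 53.0 CPM in wild type and 243 ± 127 and 81.5 ± 13.7 in daf-2 (-5.59 ± 0.49), and the saposin-like gene spp-2 (X, 7315995 to 7316818) had 10.8 ± 1.89 and 272 ± 14.9 CPM against 88.0 ± 33.9 and 60.8 ± 47.8 (-5.18 ± 0.69). Positive interactions were led by comt-4 (V, 2049217 to 2050185), with 21.8 ± 19.9 and 3.09 ± 0.777 CPM in wild type and 7.32 ± 2.37 and 38.5 ± 1.98 in daf-2 (5.2 ± 0.84, adjusted p = 0.0052), followed by the acyl-CoA synthetase gene acs-2 (V, 15567394 to 15569897; 3.75 ± 0.86, adjusted p = 0.027) and the acyl-CoA dehydrogenase gene acdh-2 (II, 5544778 to 5547492; 2.88 ± 0.70, adjusted p = 0.033). The call of acs-2 was lost without wild-type day 1 replicate 2 (adjusted p = 0.0558), wild-type day 9 replicate 2 (0.0689) or 3 (0.0666), daf-2 day 1 replicate 1 (0.0743) or 2 (0.0666), or daf-2 day 9 replicate 1 (0.061), with values of 3.45 or more. That of acdh-2 was lost without any library except wild-type day 1 replicate 3, daf-2 day 1 replicate 3 and daf-2 day 9 replicates 1 and 3 (2.27 to 3.09, adjusted p = 0.0516 to 0.0778 without each of the other 8). The genes sosi-1 (I, 4460146 to 4462704; 1.91 ± 0.33) and gst-38 (V, 15915162 to 15916070; 1.89 ± 0.32) came next.

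Of the study genes, zip-10 was called in the interaction (-2.25 ± 0.46, adjusted p = 0.016), with a rise in wild type and a fall in daf-2, as were ins-7 and sysm-1 (-2.27, adjusted p = 0.03). The call of sysm-1 was lost without wild-type day 1 replicate 3 (adjusted p = 0.0616), wild-type day 9 replicate 1 (0.0552) or 2 (0.0723), daf-2 day 1 replicate 1 (0.0698) or 2 (0.0531), or daf-2 day 9 replicate 2 (0.0764) or 3 (0.0546), with values of -2.35 to -1.77. Of 59 antimicrobial genes 28 had a negative interaction and 0 a positive one (43 and 2 adjusted over the list alone), and the list was called by camera (adjusted p = 5.2e-17), with adjusted p = 0.45 with an estimated correlation. These included lys-7, which went from 97.5 ± 28.9 to 5570 ± 713 CPM in wild type and from 795 ± 55.8 to 3730 ± 871 in daf-2 (-3.61 ± 0.32, adjusted p = 0.00011), ilys-3 (-4.52 ± 0.61), ilys-2 (-6.2), ilys-5 (-4.54) and cnc-4 (-3.08). Of the 28 genes 21 rose in wild type, 4 of which fell in daf-2 and 6 of which rose in both. Without daf-2 day 1 replicate 1 the number of antimicrobial genes called was 19.

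**Figure D4:**
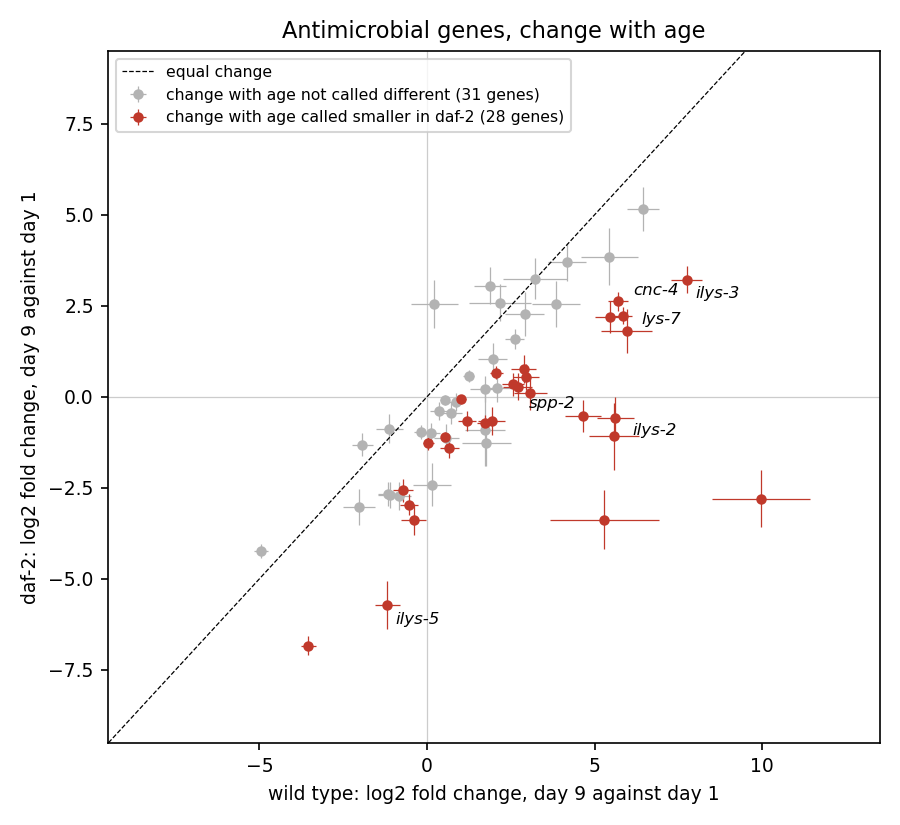
Log2 change from day 1 to day 9 of the 59 antimicrobial genes in wild type (horizontal axis) and daf-2 (vertical axis), with SE bars and a dashed line of equal change. The 28 genes with a called, negative interaction are red and lie below the line, and the other 31 are grey.

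Of 117 C-type lectin genes 15 had a negative interaction and 2 a positive one (28 and 3 adjusted over the list alone), with clec-146 (-2.27 ± 0.18, adjusted p = 8.2e-05) among the 15. Pathogen-induced genes were negative for 5 of 18 (6 adjusted over the list alone), DAF-16 targets for 6 of 25 (8 negative and 2 positive adjusted over the list alone), DAF-16-repressed genes for 4 of 17 and insulin-like peptides for 4 of 27 (8 adjusted over the list alone). Among DAF-16 targets tts-1 went from 26.6 ± 6.68 to 820 ± 65.8 CPM in wild type and from 314 ± 55.6 to 1400 ± 232 in daf-2 (-2.78, adjusted p = 0.0002). Of 22 intestinal genes 5 were negative and 0 positive (10 and 0 adjusted over the list alone), and of 37 neuronal genes 2 and 0 (4 and 0). With RLE scaling 3 intestinal and 0 neuronal genes were negative, and with reference-gene scaling 6 and 4. Lipid breakdown genes were negative for 5 of 24 and positive for 2 (7 and 3), and fatty acid synthesis genes negative for 4 of 21 (7 adjusted over the list alone), fat-7 among them (-2.55 ± 0.32). The number of fatty acid synthesis genes was 2 with RLE, 6 with upper-quartile and 7 with reference-gene scaling. Of the vitellogenins vit-2 was not called (-1.04, adjusted p = 0.196) and vit-5 was (-1.90 ± 0.43, adjusted p = 0.024), a call lost without wild-type day 1 replicate 3 (adjusted p = 0.0505), wild-type day 9 replicate 2 (0.0568) or 3 (0.0679), daf-2 day 1 replicate 2 (0.0566) or daf-2 day 9 replicate 1 (0.064), with values of -1.92 to -1.66. The other 4 were not called (adjusted p = 0.54 to 0.86). Adjusted over the list alone, 13 of 33 proteasome genes had a positive interaction, against 0 adjusted over all genes, and of 12 genes of the mitochondrial genome 1 was positive (4 adjusted over the list alone), WBGene00010967 (0.92 ± 0.18, adjusted p = 0.012). Camera called 18 lists and 0 with an estimated correlation (lowest adjusted p = 0.45), and fry called 7. Signs of median, mean and test differed for 4 lists: insulin signalling components, glutathione S-transferases, trehalose, glyoxylate and gluconeogenesis genes, and pharynx.

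Over all genes that rose in wild type, the median log2 change was 1.49 in wild type and 0.81 in daf-2. The interaction was called with a larger change in wild type for 541 of the 4848 and in daf-2 for 5. In the same order, the 3395 genes that rose in daf-2 had medians of 1.45 and 1.27, with 154 and 27 such calls. The 3970 that fell in wild type had -0.74 and -0.48, with 69 and 51. The 3330 that fell in daf-2 had -0.75 and -0.9, with 27 and 272. Choosing genes by calls in a genotype favours a larger change in it. The counts for rises in daf-2 went against this.

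**Figure D5:**
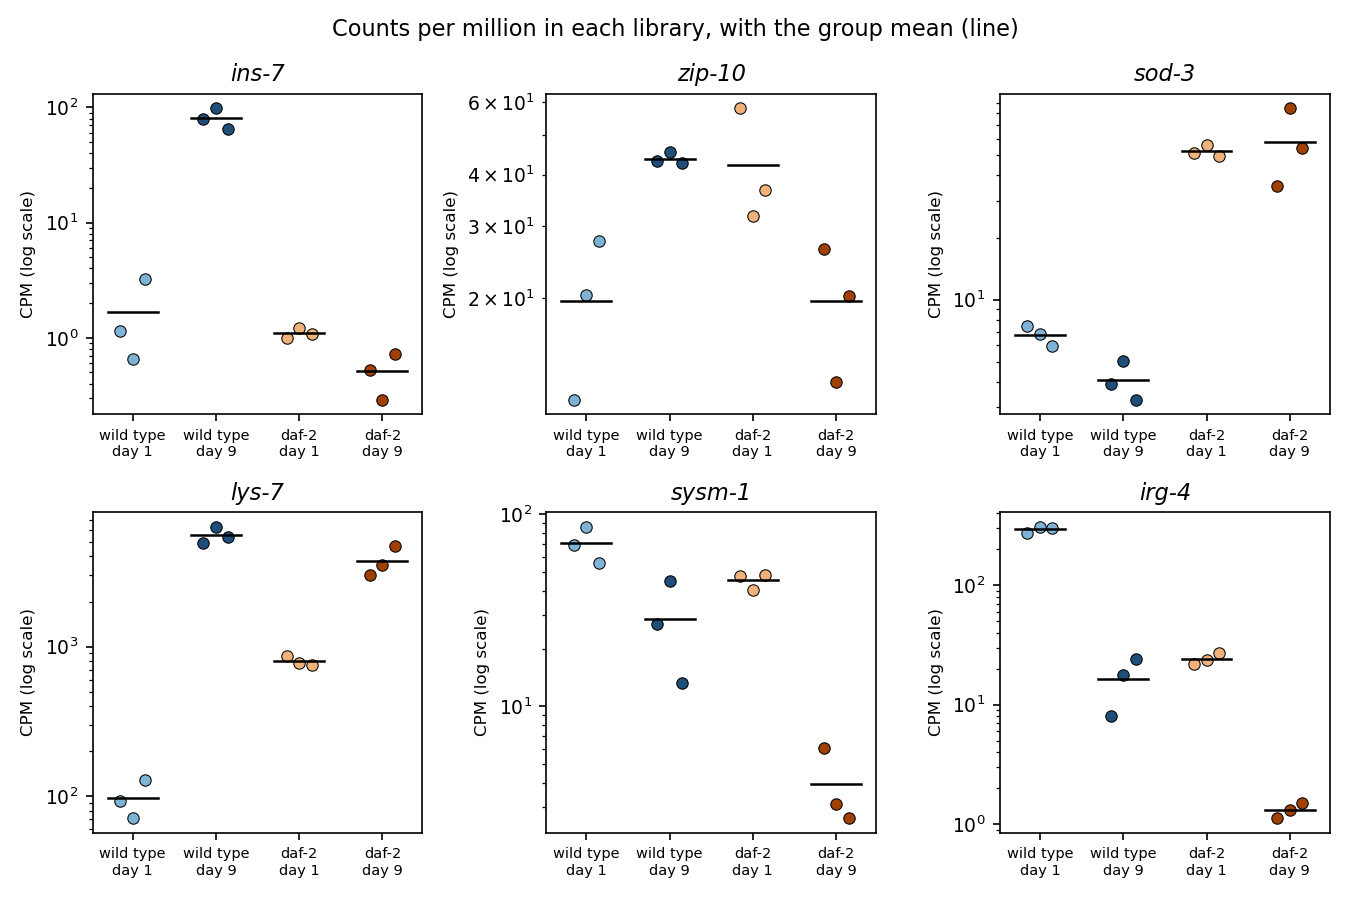
CPM on a log scale of ins-7, zip-10, sod-3, lys-7, sysm-1 and irg-4 in each of the 12 libraries, with a line at the mean of each group. Wild type at day 9 has the highest ins-7 level (80.9 CPM) and both daf-2 groups the highest sod-3 level (52.4 and 58.2 CPM).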

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

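The tests of other splits of the libraries for the counts of genes and of lists were set before their results were seen, and the tests on the antimicrobial genes were chosen only afterwards. Each result here stands out because the interaction test found a change with age that differed between the genotypes, given as the log2 change in daf-2 minus that in wild type.

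The interaction was negative for 732 genes and positive for 89. Of the 97 genes named by the rule 32 were called, 26 of them with a negative value. The values below -4 were those of ins-7 (-6.6), cpr-4 (-6.6), ilys-2 (-6.2), argk-1 (-5.87), far-3 (-5.59), spp-2 (-5.18), cpr-1 (-5.14), dct-8 (-5.05), ilys-5 (-4.54), ilys-3 (-4.52) and cpt-3 (-4.24). Smaller negative values were found for clc-24 (-3.8), lys-7 (-3.61), cnc-4 (-3.08), col-93 (-3.06), icmt-1 (-3.06), cpr-5 (-3.01), pud-4 (-2.98), tts-1 (-2.78), fat-7 (-2.55), sysm-1 (-2.27), clec-146 (-2.27), zip-10 (-2.25), dod-6 (-2.1), vit-5 (-1.9) and col-155 (-0.72). Positive values were found for WBGene00010967 (0.92), gst-38 (1.89), sosi-1 (1.91), acdh-2 (2.88), acs-2 (3.75) and comt-4 (5.2). The call of col-93 was lost without daf-2 day 9 replicate 2 (-2.78, adjusted p = 0.0546). That of cpr-5 was lost without any library except wild-type day 1 replicate 1 and wild-type day 9 replicate 3 (-3.35 to -2.58, adjusted p = 0.0543 to 0.12 without each of the other 10), and that of col-155 was lost without any library except wild-type day 1 replicates 1 and 2, daf-2 day 1 replicate 3 and daf-2 day 9 replicate 3 (-0.76 to -0.62, adjusted p = 0.0552 to 0.0921 without each of the other 8). With RLE scaling the calls of cpr-5 (adjusted p = 0.0506) and col-155 (0.0559) were lost. Also lost were that of cpr-5 with thinned libraries (0.0615) or without the day 1 libraries highest in moulting genes (0.0518) and that of col-155 with no filter (0.0558). Those of vit-5 (adjusted p up to 0.0679), sysm-1 (0.0764), acs-2 (0.0743) and acdh-2 (0.0778) were lost without single libraries too. A fit without 1 library also has fewer samples.

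Camera called 18 lists, with these median differences: antimicrobial genes -1.7, insulin-like peptides -1.08, pathogen-induced genes -0.95, intestine -0.88, DAF-16-repressed genes -0.79, moulting-cycle genes -0.65, C-type lectins -0.63, DAF-16 targets -0.61, UDP-glycosyltransferases -0.61, neurons -0.5, ribosome biogenesis 0.21, ribosomal proteins 0.23, nuclear respiratory chain 0.3, germline 0.35, proteasome 0.36, cytosolic heat shock genes 0.4, histones 0.42 and mitochondrial genome 0.57. No call held with an estimated correlation (lowest adjusted p = 0.45).

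Other splits of the 12 libraries into genotypes within each age were drawn 100 times, the real one included. Of these, 82 mixed the genotypes at both ages and called at most 1 gene. Mixing puts the difference between the genotypes into the spread between libraries, which lowers the calls by construction, and the splits did not keep the pairs of day 9 libraries, so they leave open whether chance gives as many interaction calls. The real split called 821 genes, reached by 1 of the 100, and the highest other, which kept the genotypes at day 9 and mixed them at day 1, called 695. The real split called 18 lists, reached by 24, and the highest other called 25. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For ageing in wild type the real split called 8818 genes and 20 lists, and the highest of the others 0 genes and 23 lists. For ageing in daf-2 the numbers were 6725 genes and 19 lists against 1 gene and 20 lists, for genotype at day 1 2386 and 14 against 144 and 17, and for genotype at day 9 1675 and 14 against 0 and 18. As many lists as in the real split were called by 3, 3, 7 and 6 of the 10 splits in these 4 comparisons, and as many genes by 1 in each. At day 9, 4 splits part all pairs of same-numbered libraries, and the highest of the others called 0 genes.

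The antimicrobial genes formed the clearest pattern, with 28 of 59 called at a lower change with age in daf-2 and 0 at a higher one. At day 1 the median difference of these genes, daf-2 minus wild type, was 0.80, with 19 called higher in daf-2. At day 9 it was -0.97, with 29 called lower, so both ages enter the pattern. The highest other split called 11 of the genes in 1 direction, which leaves chance open for the same reason. All 28 were still called under each of the 3 other scalings, 26 were called with all libraries thinned to the smallest total, and at least 19 were called whichever library was left out (19 without daf-2 day 1 replicate 1), which argues against scaling, depth or a single library as the whole cause. Less intestinal RNA in old daf-2 animals may account for part of it, since intestine markers outside these families also had a negative median difference (-0.81 over 21 markers), but their lower quartile was -1.44, above the antimicrobial median of -1.70. What underlies the differences between the genotypes in antimicrobial gene expression, called at both ages, was not tested and stays open, a biological difference included.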

How the results depend on the processing

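Most alternatives were set before the data were examined. The fit with thinned libraries, the fit without the day 1 libraries highest in moulting genes (wild-type replicate 1 and daf-2 replicate 3) and the 6-library fit with the block at day 9 were chosen only after the results were seen. A rounding alternative was not run, since the counts were whole numbers already. Of the calls of named genes, 2 of 36 for ageing in wild type, 3 of 33 for ageing in daf-2, 10 of 26 for genotype at day 1, 4 of 25 for genotype at day 9 and 7 of 32 in the interaction were lost under at least 1 alternative, each of them with a single library left out, which also means fewer samples. Unless a construction is named, the cause was not tested. Depth limits what can be said of genes with a count of 0, which allows up to 3 counts in a library.

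The limit of 2-fold lowers counts by its construction: 1344 genes lower for ageing in wild type, 2019 higher and 1515 lower for ageing in daf-2, 936 and 228 for genotype at day 1, 41 higher in the interaction and 2583 shared ageing genes. The stricter filter tests fewer genes, and gave 3067 higher for ageing in wild type, 459 higher for genotype at day 9 and 225 higher in the interaction. For genotype at day 1 the lower count was 1206 with RLE scaling, 302 with reference genes, 1692 with DESeq2 and 1220 without the libraries highest in moulting genes. A fit of only the 6 libraries compared gave 924 higher and 246 lower at day 1, and 1150 higher at day 9. The interaction gave 40 higher with reference genes, 449 higher and 1157 lower with DESeq2, and 299 and 1385 without the libraries highest in moulting genes.

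Leaving out 1 library at a time gave 879 (without daf-2 replicate 1) to 2044 (without wild-type replicate 1) genes higher and 239 (without wild-type replicate 2) to 1156 (without wild-type replicate 1) lower for genotype at day 1. At day 9 the ranges were 399 (without wild-type replicate 2) to 547 higher and 622 (without daf-2 replicate 2) to 875 lower. The interaction ranged from 29 (without wild-type day 9 replicate 2 or 3) to 233 (without daf-2 day 1 replicate 3) higher and from 404 (without wild-type day 9 replicate 2) to 1097 (without daf-2 day 1 replicate 3) lower.

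With the replicate block in the 12-library fit, the counts were 4870 and 4003 for ageing in wild type, 3451 and 3382 for ageing in daf-2, 1655 and 1018 for genotype at day 1, 788 and 983 for genotype at day 9, and 84 and 658 for the interaction, each within 1.5 times the count without it. At day 9 the 6-library fit with the block gave 1420 higher and 2077 lower, and the block changed no call of a named gene there, but several gene lists moved. Without and with the block in that fit, 4 and 46 of 60 sperm genes, 5 and 10 of 15 PMK-1 effectors, 10 and 17 of 60 UDP-glycosyltransferases, 2 and 4 of 33 glutathione S-transferases, 1 and 4 of 25 DAF-16 targets, 2 and 4 of 18 hypodermis genes and 0 and 2 of 23 zygotic genes were lower, and 3 and 7 of 50 histone genes and 7 and 12 of 84 collagens were higher. Elsewhere the calls of scl-19 (adjusted p = 0.0547), zip-10 (0.0549) and msp-81 (0.0522) at day 1 and of acdh-2 (0.0614) and col-155 (0.0501) in the interaction were lost with the block. At day 1, the ribosomal protein genes rpl-31 and rpl-1, not called with TMM scaling over the 12 libraries, were called with DESeq2 (-0.47 and -0.50, adjusted p = 0.0181 and 0.0308) and without daf-2 replicate 2 (0.0333 and 0.0318). The gene rpl-31 was also called with RLE (0.049) or upper-quartile scaling (0.0459), the stricter filter (0.0479) or without wild-type replicate 1 (0.0278). In no comparison did every library correlate best with the library of its own number.

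Camera called 0 lists in each of the 5 comparisons with an estimated correlation, and fry called 6 for genotype at day 1, 8 for genotype at day 9 and 7 in the interaction.

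The median of the autophagy and lysosome list for ageing in wild type (-0.17), called by camera (adjusted p = 0.034), turned to 0.01 with upper-quartile scaling. Its call was lost with the replicate block (adjusted p = 0.055) and with an estimated correlation (0.62). Among genes named by the rule, the directions that turned were those of changes that were not called. For ageing in wild type daf-16 was at 0.087 with upper-quartile scaling and 0.06 with reference genes. For ageing in daf-2 sod-3 ran from -0.22 (without daf-2 day 9 replicate 2) to 0.41. For genotype at day 1 daf-16 was at -0.046 with RLE scaling, -0.009 with no filter, -0.051 with DESeq2 and -0.107 without the libraries highest in moulting genes, and ran from -0.075 to 0.104 with a library left out. There hsf-1 was at 0.047 with reference genes and ran from -0.19 to 0.0, ins-7 ran from -1.06 to 0.25 (without wild-type replicate 3), and vit-4 was at -0.04 with RLE scaling, -0.007 with no filter and -0.045 with DESeq2 and ran from -0.185 to 0.17. In the interaction vit-3 ran from -0.71 to 0.07 and vit-6 from -0.56 to 0.11, both highest without daf-2 day 9 replicate 2.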

Other observations

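The tests on the chromosome V block and on the germline genes were chosen only after the result was seen, as were the genes named in the first paragraphs from their lists. The criteria of the germline tests were also revised after their values were seen.

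Of 24 lipid breakdown genes 5 had a negative interaction and 2 a positive one, and the list was not called by camera (adjusted p = 0.17). Of its members, the acyl-CoA oxidase gene acox-1.1 fell by 1.26 on the log2 scale in daf-2 and was not called in wild type (0.23), with an interaction of -1.49 (adjusted p = 0.00822). The genes maoc-1 and dhs-28 fell by 0.94 and 0.92 in daf-2, with interactions of -1.32 and -1.41. The selective autophagy receptor gene sqst-1 rose by 1.62 in daf-2 and 2.00 in wild type. It was higher in daf-2 at day 1 (1.18) and day 9 (0.79). The transcription factor gene hlh-30 rose by 0.94 in wild type, had a change of 0.11 in daf-2 (adjusted p = 0.529) and an interaction of -0.83 (adjusted p = 0.0243).

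The heat shock gene hsp-70 rose in both genotypes (2.81 and 3.07) and was higher in daf-2 at day 1 (1.71) and day 9 (1.97). The insulin-like peptide gene ins-22 rose in both (2.98 and 3.14) and was higher in daf-2 at both ages (3.02 and 3.19). By contrast ins-8, which missed the naming rule's level or overlap limits, rose by 7.47 in wild type. It was at -1.31 in daf-2 (adjusted p = 0.373), with an interaction of -8.78 (adjusted p = 0.0158). At day 9, 13 of 62 cytochrome P450 genes were higher in daf-2 and 8 lower (17 and 11 adjusted over the list alone), 7 of 34 glutathione S-transferases were higher and 2 lower (11 and 4), and 4 of 63 UDP-glycosyltransferases were higher and 9 lower (6 and 13).

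A block of genes on chromosome V (17339084 to 17551209) was near 0 counts in all wild-type libraries. The run of 21 neighbouring counted genes compares with a longest run of 3 in 10000 shuffles of gene order, and 1 of 42 genes within 150 kb outside the block, spp-29, had 3 or fewer wild-type counts. The smaller totals of the wild-type libraries are excluded as the cause, since daf-2 had 4800 times the wild-type counts over the block and 1.34 times the totals. A deletion in the wild-type stock is a candidate explanation: over the 60 genes inside that did not define the block, wild type had 0 counts and daf-2 255. Transcription of the block shut off in wild type cannot be told apart from it without reads of DNA, since both leave close to the 6 wild-type counts found.

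At day 1, 13 of 53 germline genes were lower and 10 of 37 neuron genes higher in daf-2, and neither list was called with an estimated correlation (adjusted p = 0.74 for each). A lower share of germline RNA could give this pattern: the median differences of intestine, pharynx, hypodermis, muscle and neuron markers were 0.16, 0.27, 0.3, 0.38 and 0.39, and while intestine fell outside the neuron quartiles (lower quartile 0.18), the neuron median lay within the wide intestine quartiles (-0.54 to 0.82), so the tissues cannot be told apart. The share of counts of the germline genes was 2.23, 2.52 and 2.54% in the wild-type day 1 libraries and 1.48, 1.84 and 2.41% in those of daf-2, which overlapped (exact two-sided permutation test, p = 0.2, 0.29 adjusted over 32 tests). The scaling of the libraries may account for part of the germline difference. The median over the 53 genes was -0.40 (quartiles -0.54 and -0.26) and -0.25 (-0.39 and -0.11) with the 3 reference genes, where 1 of the 13 genes was still called, against 13 with RLE or upper-quartile scaling. A single library may account for part as well, since the median was -0.24 (-0.38 and -0.11) without daf-2 day 1 replicate 1 and -0.32 (-0.43 and -0.20) without wild-type day 1 replicate 2, with 1 of the 13 called in each. In these 3 fits the median log2 difference of the 13 genes went from -0.58 to -0.44, -0.44 and -0.48, while their median SE (0.16) was 0.15 to 0.17, so the lost calls went with smaller differences. Without daf-2 day 1 replicate 2 or wild-type day 1 replicate 3, 4 and 6 were called, with medians of -0.65 and -0.64 and a larger SE (0.19 and 0.18). With the quartiles still below 0 and the calls lost, neither scaling nor a single library is excluded or shown as the whole cause. A biological difference in germ line size or activity stays open and was not tested.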
